A study of Rattus norvegicus with 9 samples.

How the data were processed

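The series holds 9 small RNA libraries from primary neonatal rat cardiomyocytes, 3 each of Ad-GFP, Ad-Yap WT and Ad-Yap shRNA, sampled 48 h after virus. Per the labels' protocols, libraries were made with the MGIEasy small RNA kit, size selected on a gel, amplified by PCR and read as single-end 50 base reads on a BGI instrument; the same protocol text also describes an mRNA enrichment step, and which RNA fraction it applies to is not clear from it. The submitters' processing notes name Bowtie2, DESeq2 and the rn6 genome build, with no versions, roles or order. How reads that match several miRNAs were assigned, and whether molecular identifiers were used, is not given in the sources used here.

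A single table of 1422 miRNAs was used. It gives, per library, read counts, whole numbers per miRNA as deposited by the authors and not normalized, and RPM values that the authors computed from them. Dividing the counts by the deposited RPM values gives 1 library total per library, between 13.7 and 22.1 M, which exceeds the summed miRNA counts of 1.48 to 3.60 M; what that total counts is not stated. Every per-sample column matched the labels of 1 sample. Group averages in the table were not used. The control columns carry the abbreviation that the labels give to the Ad-GFP group.

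Tests were run on the deposited counts with edgeR 4.0.16 in R 4.3.3: filterByExpr left 579 miRNAs (428 annotated, 151 predicted), library sizes were scaled by TMM among the miRNAs, and glmQLFit and glmQLFTest were fitted to all 9 libraries with 1 mean per group, so that the groups share the estimate of spread (common biological CV 45.1%). p-values are two-sided and adjusted by Benjamini-Hochberg over the tested miRNAs of a comparison, with a threshold of 0.05; SE is the log2 fold change divided by the square root of F. Single values per library were compared by exact permutation tests, where 3 against 3 cannot go below 0.1. CPM values are TMM scaled reads per 1e+06, and values are mean ± SD over 3 libraries. Reads amplified by PCR are not independent molecules, so low counts are less precise than their number implies. At this depth, with 579 simulated miRNAs of which 200 were changed, 2-fold changes were recovered in 46.3% for Ad-Yap WT against Ad-GFP, 35.5% for Ad-Yap shRNA against Ad-GFP and 50% for the 2 manipulations, and 4-fold changes in 89.1%, 78.1% and 85.9%; false calls were 4.21%, 9.78% and 1.09%. A planted list was found in each simulated comparison, with 0 other lists called. Each miRNA was drawn independently there, in 1 draw per comparison. This therefore does not test list calls where members are correlated, as was estimated for several lists here.

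The groups, tests, alternatives, miRNA lists and naming rule were set before the data were examined. Of 25 lists, 22 had at least 3 tested members: striated muscle, smooth muscle and pericyte, fibroblast and mesenchymal, blood cell, epithelial and neuronal miRNAs, the let-7, miR-29, miR-30, miR-34 and miR-181 families, the family of miR-15, miR-16, miR-195 and miR-497, the miR-130, miR-301, miR-148 and miR-152 families, the miR-17-92 cluster and paralogs, the clusters of miR-23, miR-27 and miR-24, of miR-132 and miR-212, of miR-221 and miR-222 and of miR-183, miR-96 and miR-182, the Dlk1-Dio3 imprinted cluster, inflammation linked miRNAs, miRNAs reported to target Sirt1, and mirtrons with other Drosha or Dicer independent miRNAs. Endothelial miRNAs had 2 tested members, hypoxia linked miRNAs 1, and the list of miR-302, miR-367 and miR-290 had 0 in the table. Lists overlap, and cardiomyocytes also express members of the lists of other cell types. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, again with an estimated correlation, and with fry; none of the camera calls held with an estimated correlation. Libraries of 3 against 3 do not overlap in 10% by chance. Of all tested miRNAs, 47.3% did not overlap for Ad-Yap WT against Ad-GFP, 55.3% for Ad-Yap shRNA against Ad-GFP and 43.4% for the 2 manipulations. The naming rule took, per comparison, annotated miRNAs past the threshold whose libraries did not overlap: the 8 largest rises and 8 largest falls with a mean of at least 10 CPM, and the 8 most abundant. It also took miR-22-3p and miR-22-5p, up to 4 members of each list by smallest p, and up to 8 miRNAs with opposite directions.

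Alternatives were DESeq2 1.42.0, RLE, upper quartile and no scaling factors, 2 other filters, fits of 2 groups, a block for the replicate number, a fold threshold, each library left out, limma-voom, and predicted miRNAs left out. Added after the data were seen were scaling by the deposited library totals, cyclic loess on log2 of counts plus 0.5, and leaving out 28 entries whose scaled counts differed over 8-fold within a group with a count over 300. After their values were seen, a looser bound was tried for the test of shared reads. A further test of the count of miR-22-3p against depth was also added. Both were withdrawn, for both the bounds written earlier stand, and the values of these looks are described without a verdict. The spread of the median difference between predicted and annotated entries was estimated, also after its value was seen, from 2000 bootstrap draws. This spread was then added to the bound written before, under which a negative difference in either comparison counts against the explanation. Gene neighbourhood was taken from RefSeq names on the assembly GRCr8, which differs from rn6, so no coordinates are given.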

Results

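Small RNA was sequenced in 9 libraries of primary neonatal rat cardiomyocytes, heart muscle cells isolated from newborn Sprague Dawley rats, 48 h after adenoviral delivery. Ad-GFP, a virus carrying green fluorescent protein, was the control. Ad-Yap WT was used to overexpress Yap, a transcriptional co-activator of the Hippo pathway, and Ad-Yap shRNA to knock it down, with 3 libraries per group. The series title places Yap upstream of miR-22-3p and the deacetylase Sirt1 in diabetic cardiomyopathy, and the cells profiled here were kept in normal glucose. The deposited table listed 1422 miRNAs, of which 653 carried an annotated name and 769 were predicted entries, and 579 passed the expression filter. Summed miRNA counts were 3.54 ± 0.052 M reads (M = 1e+06) per library in Ad-GFP, 2.34 ± 0.54 M in Ad-Yap WT and 1.73 ± 0.32 M in Ad-Yap shRNA (SD, n = 3 each). Single libraries held from 1482367 to 3599483 miRNA reads. Yap mRNA is not part of a miRNA table, so the overexpression and the knock-down could not be checked here. Nothing in the labels says that the replicates came from separate isolations, so the p-values measure only the spread between these libraries, which may be technical.

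The listed miRNAs made up a smaller part of the libraries in both Yap groups. The deposited RPM values imply library totals of 13.97 ± 0.32 M in Ad-GFP, 19.5 ± 2.7 M in Ad-Yap WT and 20.9 ± 0.36 M in Ad-Yap shRNA (SD, n = 3). Of these totals, the listed miRNAs took 25.4 ± 0.77% in Ad-GFP, 12.5 ± 4.6% in Ad-Yap WT and 8.26 ± 1.4% in Ad-Yap shRNA. Every Yap library lay below every Ad-GFP library, and the two-sided exact permutation p was 0.1 for each Yap group, the smallest that 3 libraries against 3 allow. The most abundant entries by mean normalized count were miR-22-3p, miR-26a-5p, miR-3557-5p, let-7f-5p, the cardiac miR-499-5p, let-7c-5p, miR-21-5p, let-7i-5p, miR-99a-5p and miR-24-3p. Together the 10 most abundant entries of a library held 27.3 ± 0.27% of its counts in Ad-GFP, 33.1 ± 2.9% in Ad-Yap WT and 37.2 ± 1.5% in Ad-Yap shRNA (SD, n = 3).

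miR-22-3p, the miRNA named in the title, was the most abundant entry of every library. Its raw counts were 110290 ± 362 in Ad-GFP, 105240 ± 3251 in Ad-Yap WT and 100120 ± 4024 in Ad-Yap shRNA (SD, n = 3), while the summed miRNA counts differed between groups and libraries as given above. Its direction therefore depended on the scaling. CPM values below are reads scaled by TMM among the miRNAs to 1e+06 per library. On that scale miR-22-3p stood at 25236 ± 839 CPM in Ad-GFP, 47437 ± 13320 CPM in Ad-Yap WT and 72698 ± 14660 CPM in Ad-Yap shRNA. Between libraries of 1 group over 1.3-fold apart in miRNA depth, its count followed only 7.24 to 16.3% of the log2 depth difference. Its CPM thus rose as depth fell even between replicates, from 32783 in Ad-Yap WT replicate 1 to 58820 in replicate 2. The rises of miR-22-3p below therefore cannot be told apart from the lower depth of the Yap groups. The edgeR log2 fold change was 0.91 (SE 0.23, adjusted p = 0.0245) with Ad-Yap WT and 1.53 (SE 0.23, adjusted p = 0.00163) with Ad-Yap shRNA, and every Yap library lay above every Ad-GFP library. The deposited RPM values ran the other way, at 7900 ± 186, 5494 ± 940 and 4784 ± 119 RPM in the same order of groups, and edgeR with those library totals gave log2 fold changes of -0.52 (adjusted p = 0.102) and -0.72 (adjusted p = 0.0227). In both scalings its log2 fold changes with overexpression and with knock-down had the same sign. The Ad-Yap WT libraries did not differ from the Ad-Yap shRNA libraries past the threshold (edgeR log2 fold change -0.62, SE 0.23, adjusted p = 0.079). That difference did pass with DESeq2 (adjusted p = 0.0467), with a replicate block (0.0432), and without Ad-Yap WT replicate 2 (0.0435) or Ad-Yap shRNA replicate 1 (0.0495). The other arm of the precursor, miR-22-5p, stood at 124 ± 3.1, 108 ± 9.5 and 107 ± 17 CPM and passed in neither comparison with Ad-GFP after TMM scaling (edgeR log2 fold changes -0.19 and -0.20, adjusted p = 0.37 and 0.312). The edgeR call of miR-22-3p with Ad-Yap WT ended without Ad-GFP replicate 1, 2 or 3 (adjusted p = 0.0835, 0.0718 and 0.0635) and without Ad-Yap WT replicate 2 or 3 (0.0708 and 0.0755). Over all its alternatives the adjusted p ran from 0.00143 to 0.102.

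**Figure D1:**
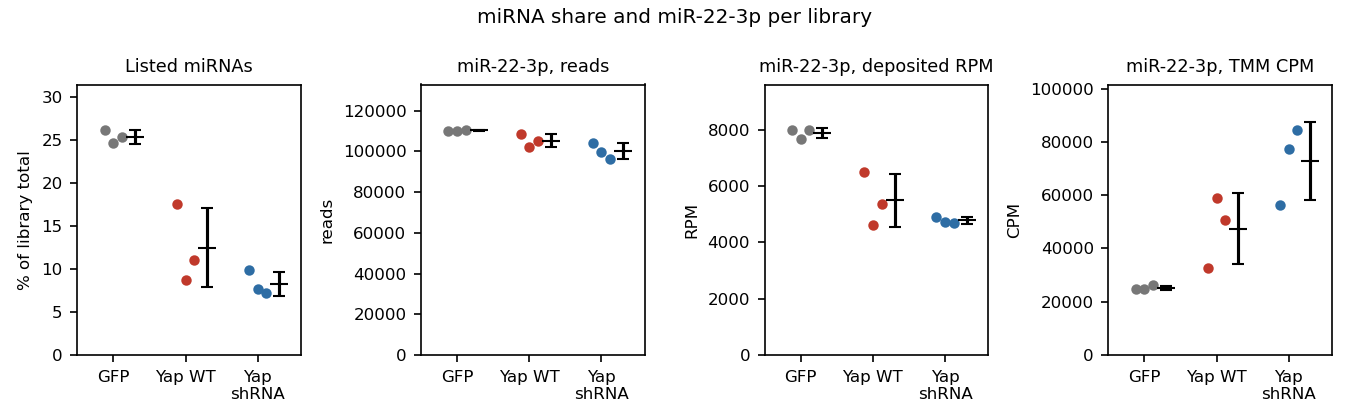
Per library, the share of the deposited library total taken by the listed miRNAs (%), and miR-22-3p as raw reads, as deposited RPM and as TMM-scaled CPM; points are libraries, and the bars give the mean and SD of 3 libraries per group. Raw reads of miR-22-3p stay between 96291 and 110698, so the deposited RPM falls in both Yap groups while the TMM-scaled CPM rises.

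Yap overexpression was compared with Ad-GFP to find the miRNAs that change when Yap is raised. Among annotated miRNAs with at least 10 CPM named by the rule, and leaving miR-125b-5p aside, the strongest rises were in miR-146a, an NF-kB induced regulator of inflammatory signalling. miR-146a-5p went from 1001 ± 104 to 4231 ± 210 CPM (SD, n = 3; edgeR log2 fold change 2.08, SE 0.11, adjusted p = 6.64e-05), and its other arm miR-146a-3p rose by 2.38. The miR-34 family, known as targets of the tumour suppressor p53, rose with it, as did miR-96-5p (1.64), miR-182 (1.52), miR-215 (1.56), miR-384-3p (1.40) and miR-34a-3p (1.67, log2 fold changes). The largest falls by the same rule were smaller, and several were in miRNAs of the imprinted Dlk1-Dio3 region. miR-127-3p fell from 2552 ± 181.5 to 1310 ± 91.6 CPM (edgeR log2 fold change -0.96, SE 0.10, adjusted p = 0.000648). miR-339-3p (-1.07), miR-760-3p (-1.07), miR-3585-3p (-1.03), miR-493-5p (-1.02), miR-540-3p (-0.99), miR-1843a-3p (-0.95) and miR-431 (-0.90) were the other large falls. Of these, the calls of miR-493-5p, miR-540-3p, miR-1843a-3p and miR-431 ended in 4, 6, 5 and 7 of the 9 runs that left out 1 library. The call of miR-182 ended without Ad-Yap WT replicate 3 (adjusted p = 0.0527) and that of miR-760-3p without Ad-GFP replicate 3 (adjusted p = 0.0519).

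Of the 40 tested members of the Dlk1-Dio3 cluster, 13 fell, 1 rose and 26 did not pass with Ad-Yap WT, with a median log2 fold change of -0.56; adjusted over the list alone, 19 fell and 2 rose. Among them miR-379-5p fell by 0.57 and miR-433-3p fell by 0.87, while miR-154-3p rose by 0.98. The list was lower than the other miRNAs by camera (adjusted p = 6.09e-05), and the adjusted p was 0.295 with an estimated correlation. All 4 tested arms in the miR-34 list rose, also when adjusted over the list alone: miR-34b-5p by 1.37, miR-34c-3p by 1.33, miR-34c-5p by 1.27 and miR-34a-5p by 0.94. The calls of miR-34c-5p and miR-34a-5p ended in 5 and 2 of 9 runs without 1 library, and the list passed (camera adjusted p = 0.00395, adjusted p = 0.238 with an estimated correlation). Among 6 inflammation linked miRNAs, miR-146a-5p, miR-146b-5p (1.21), miR-155-5p (0.83) and miR-21-5p (0.69) rose, and the same count of 4 was reached when adjusted over the list alone (camera adjusted p = 0.0181, adjusted p = 0.254 with an estimated correlation). In the cluster of miR-221 and miR-222, known to repress a cell cycle inhibitor, miR-222-3p rose from 6058 ± 238 to 12870 ± 1160 CPM (1.09) and miR-221-3p by 1.03, 2 of 3 members, also adjusted over the list alone (camera adjusted p = 0.0452, adjusted p = 0.269 with an estimated correlation). The list no longer passed with RLE factors (camera adjusted p = 0.0503), predicted miRNAs left out (0.0562), the replicate block (0.0592), at least 10 CPM in 3 libraries (0.0652), 2-group fits (0.0667) or cyclic loess (0.0875). It also missed the threshold without Ad-Yap WT replicate 1 or 3 (camera adjusted p = 0.056 and 0.0717) or Ad-Yap shRNA replicate 2 or 3 (0.0503 and 0.0562). miR-7a-5p, abundant in neurons and neuroendocrine cells, rose by 1.36, miR-92b-3p by 1.24, miR-138-5p by 1.00, miR-29b-3p by 0.87 and miR-18a-5p by 0.54. The call of miR-29b-3p ended without Ad-GFP replicate 2 or Ad-Yap WT replicate 3 (adjusted p = 0.0529 and 0.0527).

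The 8 most abundant miRNAs past the threshold all rose modestly with Ad-Yap WT, by 0.50 for miR-99a-5p, 0.52 for let-7c-5p, 0.54 for let-7i-5p, 0.57 for miR-26a-5p, 0.60 for let-7f-5p, 0.62 for miR-3557-5p, 0.69 for miR-21-5p and 0.91 for miR-22-3p (edgeR log2 fold changes). Within the Ad-Yap WT group all 8 had their lowest CPM in the deepest library, replicate 1. How much of these 8 rises comes from the lower miRNA depth of that group therefore cannot be told. Each of these 8 calls ended in at least 2 of the 9 runs that left out 1 library, and after cyclic loess scaling, which removes a trend of fold change with abundance, miR-26a-5p, miR-3557-5p, let-7c-5p, let-7i-5p and miR-99a-5p no longer passed. miR-125b-5p met the naming rule too, at 7.20 (SE 2.2, adjusted p = 0.0495), but its counts jump between libraries of 1 group while their sum with those of miR-3588 varies less, and it is reported as uncertain. The sum of both entries gave 0.71 (SE 0.34, adjusted p = 0.166). In total edgeR called 145 of 579 miRNAs, 89 higher and 56 lower, of which 48 rises and 7 falls were at least 2-fold, and 228 had an unadjusted p under 0.05. The split depended on the scaling: 74 higher and 71 lower with upper quartile factors, 51 and 104 with library size only, and 10 and 312 with the deposited library totals. These totals move the miRNAs of a library nearly alike, and the median log2 fold change of all miRNAs lay at -1.26 with them, a shift of -1.29. Through this common shift 42 of the 105 named miRNAs changed sign, which tests no single miRNA. Sign changes of miRNAs called under neither scaling were not counted. The count fell to 71 without Ad-Yap WT replicate 3, and to 83, 96 and 96 without Ad-GFP replicates 1, 2 and 3.

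Yap knock-down was compared with the same control to find the miRNAs that change when Yap is lowered. No virus with a non-targeting shRNA is among the groups. In this and the other comparison with Ad-Yap shRNA, an effect of lower Yap therefore cannot be told apart from one of expressing an shRNA. Among annotated miRNAs with at least 10 CPM named by the rule, the largest fall was in miR-204-5p, which is processed from an intron of Trpm3, from 5401 ± 62.5 to 730 ± 10.2 CPM (SD, n = 3; edgeR log2 fold change -2.89, SE 0.12, adjusted p = 1e-05). miR-211-5p, nearly identical in sequence to miR-204-5p so that reads could be shared, fell by 2.15. The fibroblast enriched miR-199a-5p fell from 11750 ± 884 to 4125 ± 127 CPM (-1.51, SE 0.079, adjusted p = 2.04e-05) and miR-199a-3p fell by 1.67. miR-7a-5p rose from 1861 ± 156 to 8028 ± 528 CPM (2.11, SE 0.11, adjusted p = 2.04e-05), and miR-146a-5p rose by 1.95, close to its rise with overexpression. The other large rises were miR-146a-3p (2.11), miR-96-5p (2.07), let-7f-1-3p (1.98), miR-133a-5p (1.98) and miR-1249 (1.75), and the other large falls miR-23b-5p (-2.24), miR-674-5p (-2.19), miR-351-5p (-1.83), miR-1843a-3p (-1.78), miR-33-5p (-1.71) and miR-702-5p (-1.70, which ended without Ad-Yap shRNA replicate 1 or 3 at adjusted p = 0.0583 and 0.0585).

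Striated muscle miRNAs were higher with Ad-Yap shRNA: 6 of 9 rose, also adjusted over the list alone, and none fell. They included miR-499-5p, which is encoded in an intron of a myosin gene (19820 ± 505 to 46920 ± 4918 CPM, log2 fold change 1.24, SE 0.13, adjusted p = 0.000445), miR-1-3p (0.82), miR-133a-3p (0.56) and miR-486 (0.54), with a median of 0.56 (camera adjusted p = 0.0351, adjusted p = 0.487 with an estimated correlation). The CPM of miR-499-5p rose as miRNA depth fell between replicates of both Yap groups. How much of its rise comes from lower depth therefore cannot be told. The list no longer passed with upper quartile factors (camera adjusted p = 0.0679), 2-group fits (0.076), library size only (0.228) or cyclic loess (0.2), and with library size only miR-133a-3p and miR-486 were at -0.037 and -0.057. Library size only moves the miRNAs of a library nearly alike, to a median of -0.54 over all miRNAs in this comparison, so its values here and below follow from a common shift and test no single miRNA. Beside this, 2 of 7 fibroblast and mesenchymal miRNAs fell and 1, miR-21-5p, rose, the same counts as when adjusted over the list alone (camera adjusted p = 0.111). The falls were miR-199a-5p and miR-199a-3p, the arms of 1 miRNA. Markers of other cell types moved apart. The endothelial miR-126a-3p and miR-126a-5p rose by 0.76 and 1.10. Of smooth muscle miRNAs miR-145-5p rose by 1.16 while miR-143-3p fell by 0.32, and the blood cell miR-142-5p fell by 1.48 (a call that ended in 3 of 9 runs without 1 library). In the miR-30 family, abundant in cardiomyocytes, 5 of 7 members rose and 1 fell, the same counts as when adjusted over the list alone, led by miR-30c-5p (1.38) and miR-30a-5p (1.35), with a camera adjusted p of 0.138. In the miR-34 list 2 of 4 arms rose, also adjusted over the list alone, miR-34a-5p (0.91) and miR-34c-3p (0.50, but -0.094 with library size only), with a camera adjusted p of 0.657. Of the inflammation linked miRNAs 4 of 6 rose, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.151). Among them miR-155-5p was at 0.53, a call that ended in 5 of 9 runs without 1 library, and at -0.058 with library size only. Of 40 Dlk1-Dio3 members 6 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.151), among them miR-376a-3p (-0.97) and miR-540-3p (-1.61). In the cluster of miR-221 and miR-222, miR-221-3p passed alone of 3, at 0.40 (-0.20 with library size only), and 0 members did when adjusted over the list alone (camera adjusted p = 0.842). This call ended in 8 of 9 runs without 1 library.

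The 8 most abundant miRNAs past the threshold rose with Ad-Yap shRNA, namely miR-22-3p (1.53), miR-499-5p (1.24), miR-26a-5p (1.07), let-7f-5p (1.06), miR-3557-5p (1.03), let-7i-5p (0.94), miR-21-5p (0.78) and let-7c-5p (0.70). The 21 most abundant tested miRNAs had a median of 0.82 in this comparison (0.27 after cyclic loess scaling), and of 0.47 (0.16) with Ad-Yap WT against Ad-GFP. After cyclic loess scaling the last pair no longer passed, at 0.16 (adjusted p = 0.159) and 0.087 (adjusted p = 0.371). In both Yap groups each of the 8 named miRNAs had its lowest CPM in the deepest library, replicate 1. How much of their rises comes from the lower miRNA depth of the Ad-Yap shRNA group therefore cannot be told. miR-125b-5p again met the naming rule at 7.78 (SE 2.3, adjusted p = 0.0268) and is uncertain for the reason given above, while the sum of miR-125b-5p and miR-3588 rose by 1.14 (SE 0.35, adjusted p = 0.0296). edgeR called 242 of 579 miRNAs, 139 higher and 103 lower, with 82 rises and 48 falls of at least 2-fold and 288 at an unadjusted p under 0.05. With library size only the split was 66 higher and 221 lower, and with the deposited library totals it was 14 and 479. Those totals gave a median of -2.15, a shift of -2.19. It changed the sign of 62 of the 105 named miRNAs, counting only those called under either scaling.

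**Figure D2:**
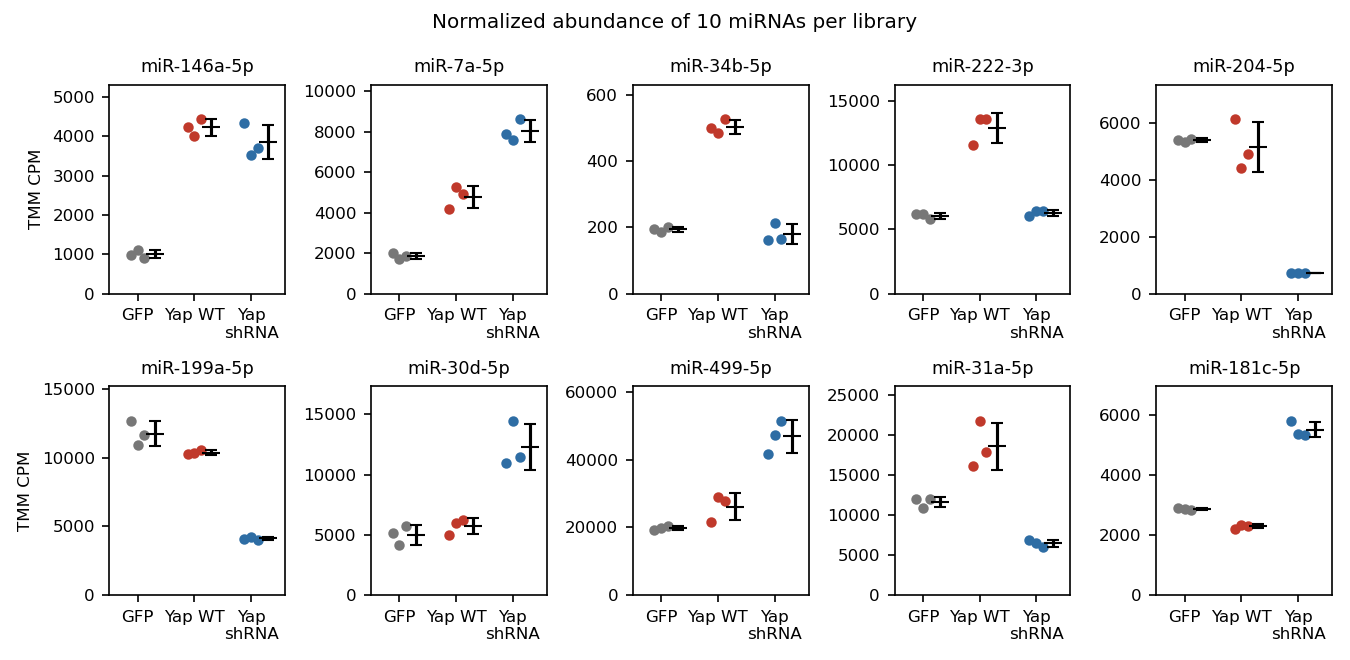
TMM-scaled CPM of 10 miRNAs in the 9 libraries; points are libraries, bars give the mean and SD of 3 libraries per group, and each vertical axis starts at 0. miR-146a-5p and miR-7a-5p are higher in both Yap groups, miR-34b-5p and miR-222-3p with Ad-Yap WT, and miR-204-5p and miR-199a-5p are lower with Ad-Yap shRNA; with the deposited library totals miR-222-3p turns to -0.25 with Ad-Yap WT, and miR-146a-5p and miR-7a-5p to -0.23 and -0.10 with Ad-Yap shRNA.

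The 2 manipulations were then set against each other, which needs no shared control. Relative to knock-down, overexpression was higher in miR-204-5p (2.82), miR-674-5p (2.22), miR-211-5p (2.06), miR-128-1-5p (1.83), miR-351-5p (1.63), miR-23b-5p (1.56), miR-384-3p (1.54) and the abundant miR-31a-5p (18540 ± 2899 against 6437 ± 436 CPM; edgeR log2 fold change 1.53, SE 0.12, adjusted p = 0.000254) and miR-322-5p (0.99). It was lower in miR-1249 (-1.62), miR-505-3p (-1.51), miR-133a-5p (-1.51), let-7f-1-3p (-1.35), miR-181c-5p (-1.27), miR-483-3p (-1.25), miR-130b-3p (-1.23) and miR-218b (-1.23). Among abundant miRNAs, miR-1b (-0.93), miR-1-3p (-0.85), miR-499-5p (-0.84), miR-181a-5p (-0.67), let-7g-5p (-0.53) and let-7f-5p (-0.47) were lower, where the 21 most abundant tested miRNAs had a median of -0.40 (-0.12 after cyclic loess scaling). Mean miRNA depth was lower with Ad-Yap shRNA. Between replicates of both Yap groups the CPM of miR-499-5p, miR-181a-5p and let-7f-5p rose as depth fell, so part of their differences may come from depth. miR-1b and miR-1-3p are close copies whose reads could be shared. The calls of miR-133a-5p, miR-130b-3p, miR-218b and let-7f-5p ended in 4, 6, 2 and 4 of the 9 runs without 1 library.

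By list, 3 of 7 fibroblast and mesenchymal miRNAs were higher with overexpression than with knock-down and none lower, and 4 when adjusted over the list alone: miR-199a-5p (1.33), miR-199a-3p (1.23) and miR-34b-3p (1.23), which also belongs to the miR-34 family (camera adjusted p = 0.0089, adjusted p = 0.27 with an estimated correlation). Striated muscle miRNAs were lower in 5 of 9, also adjusted over the list alone (camera adjusted p = 0.0226, adjusted p = 0.34 with an estimated correlation), among them miR-133a-3p (-0.87) and miR-486 (-0.56). The miR-30 family was lower in 5 of 7, and in 6 when adjusted over the list alone (camera adjusted p = 0.0089, adjusted p = 0.34 with an estimated correlation). With Ad-Yap WT against Ad-GFP these 3 lists, in the order given, had medians of 0.033, 0.074 and -0.010 and did not pass (camera adjusted p = 0.947, 0.677 and 0.677). With Ad-Yap shRNA against Ad-GFP their medians were -0.92, 0.56 and 1.15 (camera adjusted p = 0.111, 0.0351 and 0.138). The miR-34 list was higher in 3 of 4, also adjusted over the list alone (camera adjusted p = 0.0263, adjusted p = 0.27 with an estimated correlation), and the cluster of miR-221 and miR-222 in 2 of 3, also adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.27 with an estimated correlation). Of the Dlk1-Dio3 members 5 of 40 were lower, none when adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.532 with an estimated correlation). The call of the miR-221 and miR-222 list ended without Ad-Yap WT replicate 3 or Ad-Yap shRNA replicate 2 (adjusted p = 0.055 and 0.0584), and the Dlk1-Dio3 call without Ad-Yap WT replicates 2 or 3 or Ad-Yap shRNA replicate 1 (0.0797, 0.06 and 0.0569). With at least 10 CPM in 3 libraries both calls ended (0.0656 and 0.0765), and the Dlk1-Dio3 call also with predicted miRNAs left out (0.0604) and with library size only (0.149). Inflammation linked miRNAs did not pass (camera adjusted p = 0.6). edgeR called 165 of 579 miRNAs, 82 higher and 83 lower with overexpression, and 239 had an unadjusted p under 0.05. With library size only the split was 114 and 38, and with the deposited library totals 110 and 8. Those totals gave a median of 0.85, a shift of 0.89. It changed the sign of 22 of the 104 named miRNAs, counting only those called under either scaling. miR-378a-3p met the naming rule at 7.48 (SE 2.1, adjusted p = 0.0317), but its counts jump between libraries of 1 group while their sum with those of a pair of predicted entries varies less, and this sum was lower with overexpression (-0.64, SE 0.19, adjusted p = 0.0363).

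**Figure D3:**
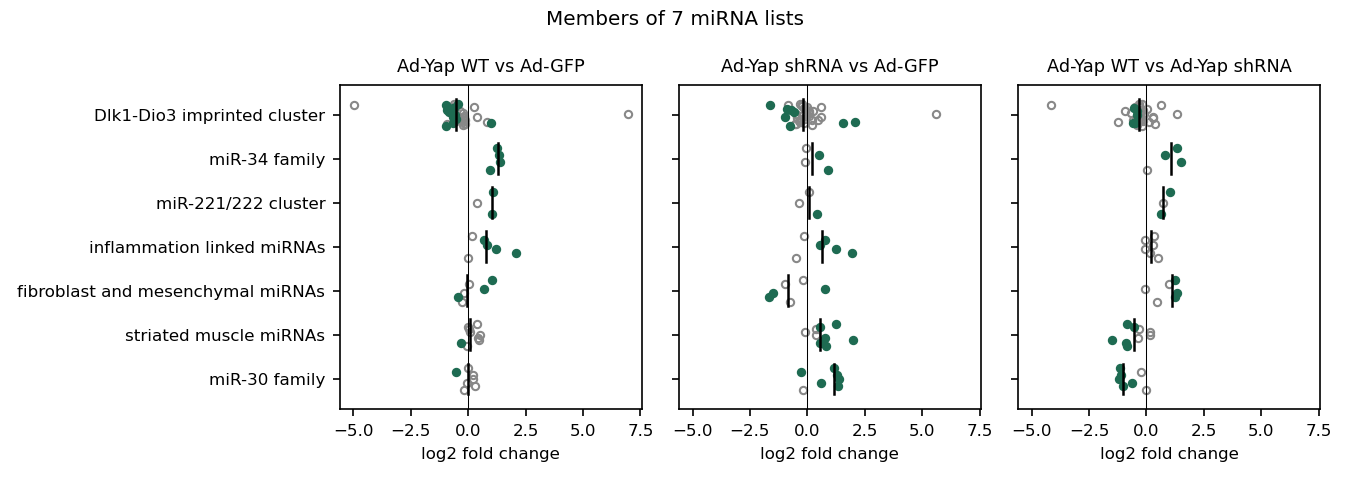
Log2 fold changes of the members of 7 miRNA lists in the 3 comparisons, leaving out entries whose scaled counts differ over 8-fold within a group with a count over 300; filled points passed an edgeR adjusted p of 0.05, open points did not, and the vertical bars are medians of the plotted members. The miR-34 arms lie to the right in the comparison of Ad-Yap WT with Ad-GFP, where with the deposited library totals miR-34a-5p, miR-34c-5p and miR-34c-3p turn to -0.43, -0.051 and -0.019, and 5 of 7 miR-30 members are filled and lie to the left where Ad-Yap WT is compared with Ad-Yap shRNA, where miR-30b-5p turns to 0.26 with those totals.

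By fry, which asks whether the miRNAs of a list moved one way and does not compare them with other miRNAs, 9, 12 and 11 of the 22 lists passed in the 3 comparisons, each camera call among them. The other lists passed camera in none of the 3 comparisons. With Ad-Yap WT against Ad-GFP some of their counts differed from those with knock-down. There, 3 of 9 miRNAs reported to target Sirt1 rose and 0 fell. In the miR-181 family 0 of 4 rose and 1 fell, and in the cluster of miR-132 and miR-212 0 of 4 rose and 0 fell. With Ad-Yap shRNA against Ad-GFP the members of these other lists moved as follows. In the let-7 family 5 of 9 rose (camera adjusted p = 0.111), with a median log2 fold change of 0.70 that was 0.087 after cyclic loess scaling. In the miR-17-92 cluster and its paralogs 8 of 12 rose and 2 fell, with miR-19a-3p (1.72), miR-106b-5p (1.08) and miR-20a-5p (0.87) among the risers (camera adjusted p = 0.138). In the miR-181 family 3 of 4 rose, led by miR-181a-5p (0.98; camera adjusted p = 0.117), while with library size only miR-181d-5p and miR-181b-5p were at -0.30 and -0.57. The call of miR-181d-5p ended in 7 of 9 runs without 1 library. In the cluster of miR-132 and miR-212, 2 of 4 fell, miR-212-3p (-1.09) and miR-132-5p (-0.85), and 3 when adjusted over the list alone (camera adjusted p = 0.117). In the miR-15, miR-16, miR-195 and miR-497 family 2 of 6 fell, miR-322-5p (-0.70) and miR-497-5p (-0.72), and miR-16-5p rose by 0.74 (camera adjusted p = 0.523), though not after cyclic loess scaling (0.16, adjusted p = 0.258). In the clusters of miR-23, miR-27 and miR-24, 3 of 7 rose, led by miR-24-3p (1.00; camera adjusted p = 0.216). With library size only miR-23a-3p (0.55) was at -0.048, and miR-23b-3p, whose call ended in 7 of 9 runs without 1 library, turned from 0.26 to -0.22 after cyclic loess scaling and to -0.34 with library size only. The miR-130, miR-301, miR-148 and miR-152 families held 2 risers and 1 that fell, miR-148a-3p at -1.34 (camera adjusted p = 0.984). The cluster of miR-183, miR-96 and miR-182 held 2 risers, miR-96-5p and miR-182 (camera adjusted p = 0.205). Of 9 tested miRNAs reported to target Sirt1, 4 rose and 2 fell (camera adjusted p = 0.657), with miR-22-3p, miR-138-5p (1.00) and miR-181a-5p among the risers and miR-199a-5p and miR-135a-5p (-2.54) the pair that fell. The fall of miR-135a-5p was not followed in the runs without 1 library. Between the Yap groups its log2 fold change ran from 2.15 to 3.32 in those runs, so its size is poorly defined. No member of the miR-29 family passed (camera adjusted p = 0.873). Neuronal miRNAs held 2 risers of 4 (camera adjusted p = 0.151). Epithelial miRNAs held 1 of 3 that fell, miR-429 at -1.59 (camera adjusted p = 0.739), and blood cell miRNAs 1 of 6 that fell (0.365). Smooth muscle miRNAs held 1 riser and 1 that fell of 4 (camera adjusted p = 0.831), and miRNAs made without Drosha or Dicer 1 of each of 4, miR-320-3p (0.31) and miR-877 (-0.93; 0.441). The call of miR-320-3p ended in 6 of 9 runs without 1 library, and it was at -0.28 with library size only. Adjusted over the list alone, the counts of these lists differed in 4 besides the cluster of miR-132 and miR-212: 9 rose and 2 fell in the miR-17-92 list, 3 rose and 1 fell in the miR-130 list, 4 rose and 3 fell among miRNAs reported to target Sirt1, and 1 rose and 2 fell among those made without Drosha or Dicer. After cyclic loess scaling the medians of other lists were lower too: from 0.26 to 0.056 for the clusters of miR-23, miR-27 and miR-24, from 0.23 to 0.032 for the miR-130 list, from 0.62 to 0.40 for the miR-181 family, from 0.65 to 0.43 for miRNAs reported to target Sirt1 and from 0.65 to 0.30 for inflammation linked miRNAs. The striated muscle median went from 0.561 to 0.393. Medians turned sign for smooth muscle miRNAs (0.18 to -0.0875) and the cluster of miR-221 and miR-222 (0.0552 to -0.302). The single tested hypoxia linked miRNA, miR-210-3p, did not pass in the 3 comparisons (edgeR adjusted p = 0.869, 0.0684 and 0.0664). With Ad-Yap WT against Ad-GFP the endothelial miR-126a-3p and miR-126a-5p were at 0.43 and 0.82 (edgeR adjusted p = 0.0401 and 0.0477), calls that ended in 8 and 7 of 9 runs without 1 library. None of the 7 miRNAs of the pluripotency linked list of miR-302, miR-367 and miR-290 was in the table.

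A miRNA that follows Yap would move one way with overexpression and the other way with knock-down. Past the threshold in both comparisons with Ad-GFP, 56 miRNAs were higher in both, 27 lower in both and 7 opposite. Higher with overexpression and lower with knock-down were miR-31a-5p (0.68 and -0.85) and a pair of predicted entries, 1 at 0.40 and -0.43 and 1 at 0.47 and -0.44. Lower with overexpression and higher with knock-down were miR-181c-5p (-0.32 and 0.94), miR-505-3p (-0.58 and 0.93), miR-708-5p (-0.59 and 0.39) and miR-133a-3p (-0.31 and 0.56). miR-133a-3p no longer passed with knock-down after cyclic loess scaling (0.13, adjusted p = 0.167), and with library size only it and miR-708-5p (-0.21) fell below 0 there. In the 9 runs that left out 1 library the Ad-Yap WT calls of miR-505-3p, miR-133a-3p and miR-181c-5p ended in 8, 5 and 2, the Ad-Yap shRNA call of miR-708-5p in 4, and the calls of the latter predicted entry in 6 and 4. The calls of miR-31a-5p ended in none. Independent lists of these sizes would share 21.4 higher, 9.96 lower and 29.3 opposite. In 100 simulations of unchanged groups against the same controls, a mean of 0.02 miRNAs was called in the same direction and 0 opposite. With no group changed, few calls of any kind arise. These counts therefore cannot say how many joint calls the shared controls give where both groups change. Across the 579 miRNAs, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.653 and a Spearman rho of 0.607, against a simulated mean r of 0.471 (highest 0.784). Their covariance was 1.07 against 0.21 in the simulations, a difference of 0.863. The 3 controls cannot be split into 2 sets of 2 libraries, so part of the excess may come from the shared controls. With the deposited library totals 310 miRNAs moved in the same direction and none in opposite ones, and the opposite count was 2 without Ad-GFP replicate 1 and 3 without Ad-GFP replicate 2 or 3 or Ad-Yap WT replicate 3.

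**Figure D4:**
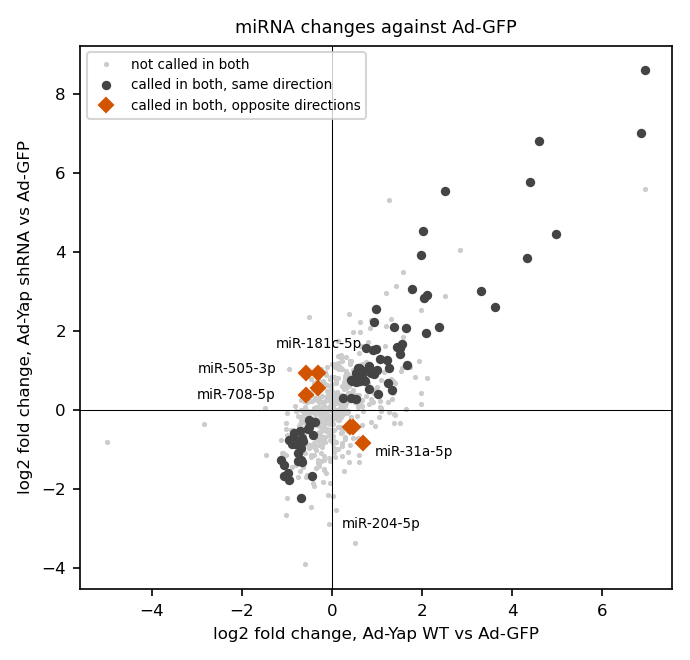
Log2 fold change of each tested miRNA with Ad-Yap shRNA (vertical) against that with Ad-Yap WT (horizontal), both relative to Ad-GFP with TMM scaling, leaving out entries whose scaled counts differ over 8-fold within a group with a count over 300. Dark points passed in both comparisons in the same direction, and the 7 diamonds passed in opposite directions.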

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

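In this part the tests of deeper sequencing and of the Yap level were chosen after the result was seen, and the test on predicted entries before, its bootstrap SE and the shares of predicted entries afterwards. The part of the deposited library total that lies outside the listed miRNAs is not itemised in the table and lies outside the miRNA counts that edgeR tested, and it was larger in both Yap groups than in the controls: a mean of 87.5% with Ad-Yap WT and 91.7% with Ad-Yap shRNA against 74.6% with Ad-GFP. Deeper sequencing of an unchanged mix would keep the share and raise the summed miRNA counts, which were 0.661 and 0.489 of the Ad-GFP mean, and so it is argued against as the whole cause. A share that rises or falls throughout with the Yap level is argued against only if both viruses changed Yap as named, which the table cannot show: the highest Yap library, at 17.6%, lay below the lowest Ad-GFP library, at 24.6%; both statements rest on the values in which the difference was seen and support no other explanation. Fragments of other RNAs counted in part as predicted miRNAs should keep predicted entries above annotated ones of like abundance in both groups. The median difference was 0.283 on the log2 scale with Ad-Yap WT (bootstrap SE 0.123, permutation p = 5e-04, the smallest that 2000 permutations give). With Ad-Yap shRNA it was -0.020 (bootstrap SE 0.159, permutation p = 0.899). Under the bound written before, this negative value counts against such fragments. The SE was added to that bound only after the value was seen, and with it the test was too wide to decide. Leaving out those that jump within a group, predicted entries held 1.65 to 1.97% of the counts in Ad-GFP, 1.90 to 2.17% in Ad-Yap WT and 2.91 to 4.32% in Ad-Yap shRNA. What stays open is such fragments, a difference in RNA or library preparation between the groups, virus-related RNA, or an effect of either manipulation, of which the last 3 could not be tested because the remainder is not itemised in the table.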

How the results depend on the processing

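The library totals, cyclic loess and jumping-entry settings were chosen after seeing the data, and the others before. Counts of calls stayed within 1.5 times of the main count except as follows, and where not stated the cause was not tested. Without a filter, where more entries are tested, 90 miRNAs were called for Ad-Yap WT against Ad-GFP, 2 were opposite, the correlation was 0.482 and 4 lists passed for Ad-Yap shRNA against Ad-GFP. An added fold threshold of 1 on the log2 scale by construction left 55, 130 and 80 calls and 0 opposite, and ended the call of miR-22-3p with Ad-Yap WT at 0.91. The deposited library totals gave 322 and 493 calls against Ad-GFP, 0 opposite, miR-22-3p at -0.52 and -0.72, and miR-22-5p, now past the threshold, at -1.53 and -2.37; these totals lower the miRNAs of the Yap groups against Ad-GFP by construction. The correlation moved to 0.577 with DESeq2, 0.509 without predicted miRNAs and 0.735 without the entries that jump within a group. For Ad-Yap shRNA against Ad-GFP 0 lists passed with upper quartile factors, library size only, 2-group fits and cyclic loess. With DESeq2 miR-22-3p passed between the Yap groups at -0.58 (adjusted p = 0.0467; 0.0432 to 0.567 over alternatives).

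With library size only, miR-22-5p passed for Ad-Yap shRNA at -0.79 (edgeR adjusted p = 0.0101). Of the named miRNAs called under either scaling, 13 crossed 0 in that comparison through a common shift to a median of -0.54, which tests no single miRNA: miR-133a-3p (-0.037), miR-486 (-0.057), miR-9a-3p (-0.015), miR-34c-3p (-0.094), miR-23a-3p (-0.048), miR-23b-3p (-0.34), miR-181d-5p (-0.30), miR-181b-5p (-0.57), miR-221-3p (-0.20), miR-222-3p (-0.54), miR-155-5p (-0.058), miR-320-3p (-0.28) and miR-708-5p (-0.21). After cyclic loess miR-23b-3p (-0.22), miR-181b-5p (-0.30) and miR-222-3p (-0.30) did so. With a replicate block the calls were 132, 228 and 160, miR-22-3p passed between the Yap groups at -0.63 (adjusted p = 0.0432), 18 of 308 named results lost and 7 gained a call, and 1 list call was lost. The numbers showed no steady pairing of the libraries: correlations of same-numbered deviations ran from -0.341 to 0.342, over 0.1 in 1 of 9 pairs. Only 2 of 9 libraries correlated best with their own number. These correlations cover all tested miRNAs, entries that jump within a group included, with 3 libraries per group, so they cannot exclude a shared isolation.

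Leaving out 1 library at a time gave 71 to 148, 191 to 245 and 125 to 164 calls, 2 to 7 opposite, a correlation of 0.576 to 0.733, and 3 to 4, 1 to 2 and 5 to 6 lists. miR-22-3p ran from 0.72 to 1.12, 1.43 to 1.70 and -0.80 to -0.40, and miR-22-5p from -0.26 to -0.12, -0.29 to -0.065 and -0.13 to 0.090; between the Yap groups miR-22-3p passed without Ad-Yap WT replicate 2 (adjusted p = 0.0435) or Ad-Yap shRNA replicate 1 (0.0495). Outside the fold threshold and the library totals, 109 of 197 called named results and 7 of 11 list calls held in every setting where they were tested. The 197 leave out miR-22-3p and miR-22-5p. With predicted miRNAs left out 191 of them were tested, and 193 without the entries that jump within a group. Lists were not run with DESeq2, the fold threshold or the library totals, limma-voom is their main setting, and the pseudocount alternative did not apply to counts. Small changes were the least detectable at this depth, spread and number of libraries, which were not varied: the simulations recovered 4.69%, 17.2% and 8.06% of 1.5-fold changes.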

Other observations

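The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. Some predicted entries rose with both viruses: 11 of 146 predicted and 2 of 405 annotated miRNAs, miR-146a-3p and miR-7b, were called higher with a log2 fold change over 2 in both comparisons with Ad-GFP, leaving out entries that jump within a group. Of the 11, 5 had a mean under 10 reads in Ad-GFP and 1 of these had none, so their fold changes are poorly defined. Of the 3 with most reads in Ad-GFP, 1 had 99 to 130 reads in Ad-GFP, 1276 to 1702 in Ad-Yap WT and 2314 to 4766 in Ad-Yap shRNA. Another had 144 to 220, 719 to 2233 and 1617 to 4048 reads, and the other 281 to 345, 520 to 1194 and 3966 to 5886. These were singled out after their values were seen, and their sequences were not used here. With the deposited library totals the median log2 fold change over all miRNAs lies at -1.26 and -2.15.

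miR-22-3p was above Ad-GFP in both Yap groups after TMM scaling. With the deposited library totals its log2 fold changes were -0.524 and -0.724, but the fall of its deposited RPM had been seen before and these totals move the miRNAs of a library nearly alike, so whether the rise comes from the choice of scaling cannot be told apart from a change of miR-22-3p. Its log2 fold changes exceeded those of miR-22-5p by 1.1 and 1.73 (SE 0.27 for each), but a ceiling on the counts of abundant miRNAs stays open and would give such a gap, so more precursor at unchanged turnover of its arms stays open too. Between libraries of 1 group that differ over 1.3-fold in miRNA depth, the 20 most abundant miRNAs differed less than those of middle abundance by 0.194 to 0.469. The smallest of these was short of the 0.2 set as needed in every pair. The count of miR-22-3p followed 7.24 to 16.3% of the log2 depth difference. This last value, looked at afterwards, shows a count that barely tracked depth between replicates, and does not tell a ceiling from other causes.

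Some entries jumped between libraries of 1 group. let-7a-5p ran from 436 to 98745 reads and miR-3596a from 276 to 97017, with within-group SDs of 2.92 and 3.23 on the log2 scale, while their sum had an SD of 0.157. The sums of miR-378a-3p with a pair of predicted entries and of miR-125b-5p with miR-3588 had SDs of 0.246 and 0.47. Reads that match several entries may have been given to 1 of them in each library: the largest ratio of a sum's SD to that of its steadiest entry was 0.137, above the 0.1 it had to stay under, so this cannot be told apart from other causes on these sets, which were picked from the counts. No biological explanation was tested. A look at the 50 most abundant other entries, made afterwards, gave a median SD of 0.142 and a highest SD of 0.864, and is not used as a test.

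A hypothesis is that neighbouring miRNA genes share a primary transcript and change together. The median difference in log2 fold change over 574 pairs within 10 kb lay at percentile 0 of 10000 random draws in each comparison, and over 223 pairs outside the Dlk1-Dio3 cluster at percentile 0, 0 and 3.5. Across the 574 pairs, which are not independent, the fold changes of neighbours had correlations of only 0.018, 0.082 and 0.17, and across the 223 pairs of 0.35, 0.299 and 0.364; members of several clusters had been seen before, so the hypothesis stays open. Another hypothesis is fewer non-muscle cells in the Ad-Yap shRNA cultures behind lower fibroblast and higher muscle miRNAs. A loss of all non-muscle cells alike is argued against, because 3 endothelial or smooth muscle miRNAs rose: miR-126a-3p, miR-126a-5p and miR-145-5p, at 6315, 496 and 10530 CPM, although with library size only both miR-126a arms (0.16 and 0.52) no longer passed, around a median of -0.54 over all miRNAs. Other values go with the hypothesis: the smooth muscle miR-143-3p (-0.32) and the blood cell miR-142-5p (-1.48) fell, and the blood cell list had a median of -0.53. Of these, miR-143-3p and the blood cell list were not particular to knock-down. With Ad-Yap WT against Ad-GFP miR-143-3p was at -0.412 to -0.338 in the runs without 1 library, and the blood cell median was -0.458. Nor were the rises of miR-126a-3p and miR-126a-5p, the arms of 1 miRNA. In those runs with Ad-Yap WT they were at 0.352 to 0.549 and 0.607 to 1.02. Cardiomyocytes may hold some of the miRNAs of other cell types too, so the 3 rises do not exclude a change of the fibroblast part, or of some cell types and not others.

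The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. As many calls came from 1 split, the real one, with 145, 242 and 165 calls, and the highest other splits gave 2, 0 and 0.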
